A study of Homo sapiens with 4 samples.

How the data were processed

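RNA was measured in Caco-2 cells, an established human colorectal adenocarcinoma line that takes on features of absorptive enterocytes after confluence. Per the labels, 4 culture conditions were profiled, made of 2 growth supports and 2 treatments, with 1 array for each condition. The supports were regular 6-well plates and collagen-coated Transwell inserts, porous membranes that give the cells separate apical and basolateral compartments. Cells received vehicle or 2 mM cholate, the sodium salt of the primary bile acid cholic acid, for 3 h, in the apical compartment on the inserts. The cholate was dissolved in a buffered salt solution without calcium, and whether the vehicle was the same solution is not given in the sources used here. Each array held labelled cDNA from a pool of RNA from 3 samples, prepared from total RNA without removal of ribosomal RNA. The sample labels give 21 days of differentiation for every condition, whereas the growth protocol gives 14 days after seeding for plates and 14 to 21 days for inserts. Support, collagen coating and possibly culture age therefore cannot be separated.

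The deposited values are log2 intensities, 1 per probe set and array, which the authors made with RMA per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of a probe set. Its software, version and probe set definition are not given in the sources used here. Normalization of this kind forces similar distributions on the arrays, so a change shared by most transcripts would not be seen. It also compresses differences near background, so a difference from or to a value under the floor can understate its size. The medians of the 4 arrays lay between 5.64 and 5.73, and between 55 and 118 of the 33297 probe sets had exactly the same deposited value, to its last digit, in any given pair of arrays. The number of arrays limits the precision, since pooling removed the spread between cultures and no condition was measured again.

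Gene names came from the platform annotation that pairs probe sets with genes, checked by gene number against a RefSeq table of assembly GRCh38.p14. Of 33297 probe sets, 19460 had 1 gene symbol, 1754 had several and 12083 had none listed. Controls and intronic probe sets among the unlisted ones were not told apart. Of the probe sets with 1 symbol, 19429 were found in the RefSeq table and 0 needed a new name. Probe sets with several symbols were counted but not named. For the 18417 genes with 1 symbol, the probe set with the highest mean over the 4 arrays stood for the gene. No genomic positions are given because the build of the probe sets was not stated.

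Probe sets entered the counts when their mean over the 4 arrays was at or above the 40th percentile, which was a log2 intensity of 4.84 and left 19978 probe sets, 14780 of them with a listed gene. With 1 array per condition, differences between 2 conditions are log2 differences with no replicate check and no p-value, and probe sets at least 1.5-fold apart were counted. The test across all 4 arrays used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on an additive model of support and treatment, 2-sided, with Benjamini-Hochberg adjusted p under 0.05. Its 1 residual degree of freedom is the difference between the 2 cholate responses, which stands in for the error, so a gene that answers on 1 support more than on the other counts as noisy. The prior had 2.83 degrees of freedom. All standard errors below come from this fit and do not measure the spread between cultures.

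The 35 gene lists were fixed before the data were examined. For each list the median log2 difference over all measured members was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile among these describes the 4 arrays and is not a test of the conditions. Members of a list can be regulated together, which random lists do not share. Counts of members higher or lower in both pairs of arrays were not set against random lists. Among all probe sets with a listed gene above the floor, 61.0% had the same sign in both cholate responses and 72.3% in both support differences. Of 15 adherens junction and desmosome genes, 10 were lower and 0 higher in cholate on both supports, although that list stood at percentile 20.9. Only members above the floor were tested with limma. Those passing were counted with adjustment over all probe sets and over the list alone. Those adjusted counts are not corrected across the 35 lists.

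Genes are named by a rule also fixed before the data were examined, among genes above the floor with 1 symbol. For cholate, it takes the 12 highest and 12 lowest by the smaller of the 2 absolute responses among genes that went the same way on both supports. It does the same for support over the 2 treatments. It adds the 5 highest and 5 lowest for cholate on each support alone and for the difference of responses. From each list it adds up to 4 measured members with the largest absolute mean difference, for cholate and for support. The rule gave 265 genes. Small nucleolar RNAs, ACTG2, PRSS1, IFITM1, HSD17B7P2 and members of the UGT2B, CYP3A and metallothionein families resemble other genes, so their probe sets can also bind related transcripts.

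The limma step was tested on simulated data made for the cholate comparison, with 19978 probe sets in each of 10 runs. It recovered 90.6% of 4-fold changes (log2 size 2), 17.8% of 2-fold changes (log2 size 1) and 0% of 1.5-fold changes. Each simulated change had the same size on both supports. In the data the slope of the Transwell response on the plate response was 0.29 among listed genes. A response that differs between supports adds to the error, so these rates do not hold for such genes. The step called 68 of 197780 unchanged probe sets (0.03%), beside 598 recovered 4-fold and 119 recovered 2-fold changes. That 0.03% is therefore not the share of false calls among all calls. The percentile step, tested on 18417 genes, placed 20 of 20 lists shifted by 0.3 log2 outside the central 95% of random lists and 2 of 20 unshifted lists.

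Alternatives fixed beforehand were a 2-fold threshold, no floor or a floor at the 60th percentile, quantile normalization, median centring and cyclic loess between the arrays, a mean-variance trend or robust variance in limma, rank correlation, means instead of medians and list members above the floor. Counting only probe sets with a listed gene was added after seeing the data. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.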

Results

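Gene expression was profiled in Caco-2 cells grown on regular plates or on collagen-coated Transwell inserts and exposed for 3 h to vehicle or 2 mM cholate. There were 4 arrays, 1 for each combination of support and treatment, each hybridised with RNA pooled from 3 samples. No value below has a replicate check. Across the 19978 probe sets above the floor the arrays correlated at r of 0.977 to 0.993. The closest pair was vehicle and cholate on Transwell (r of 0.993), and vehicle and cholate on the plate correlated at 0.983.

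The first comparison asked which transcripts differed between cholate and vehicle on both supports, which share no array. Cholate pools had more RNA of immediate early genes, the transcription factors and feedback regulators that cells induce within minutes of a stimulus. FOSB, a subunit of AP-1, was higher by 2.39 log2 on the plate and 1.18 on Transwell (5.25-fold and 2.26-fold). EGR1, a zinc finger transcription factor, was higher by 1.08 and 1.28 log2, a mean of 1.18 with a limma SE of 0.10. NR4A2, an orphan nuclear receptor, was higher by 1.27 and 0.79, with both vehicle values (4.64 and 4.74) under the floor of 4.84 and so near background.

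The other 9 of the 12 genes highest on both supports were mostly small RNAs. They included the small nucleolar RNAs SNORD14E (3.10 log2 on the plate and 1.35 on Transwell), SNORD75 (2.46 and 0.99), SNORD77 (1.79 and 0.98), SNORD74 (2.44 and 0.89) and SNORD50B (2.37 and 0.80). Such RNAs guide the modification of ribosomal RNA and are cut from introns of host genes. MIR425, a microRNA precursor, was higher by 1.63 and 0.91, the pseudogene HSD17B7P2 by 1.51 and 0.83, and LOC731157 by 2.39 and 0.83. The Transwell vehicle value of SNORD77 (4.66) also lay under the floor. RGS2, a regulator of G protein signalling outside the fixed lists, was higher by 1.89 and 0.90.

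The 12 genes lowest on both supports were all protein-coding. KRT23, a keratin, was lower at -1.45 log2 on the plate and -1.41 on Transwell, a mean of -1.43 with a limma SE of 0.09. The membrane mucin MUC15 stood at -1.21 and -1.66, and ENPEP, the aminopeptidase that cleaves angiotensin II, at -2.02 and -1.15. GRAMD2A stood at -1.89 and -1.50, and OLFML1 at -2.58 and -1.30. The connexin gene GJA5 (-2.06 and -1.13), the actin gene ACTG2 (-1.88 and -1.10) and OLR1, a receptor for oxidised lipoprotein (-1.76 and -1.07), followed. The remaining members were the desmosomal cadherin gene DSC3 (-1.59 and -1.06), the natriuretic peptide gene NPPB (-1.05 and -1.07), the annexin gene ANXA1 (-1.79 and -1.01) and VGLL1, a cofactor of TEAD transcription factors (-1.84 on the plate, with a mean of -1.42).

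**Figure D1:**
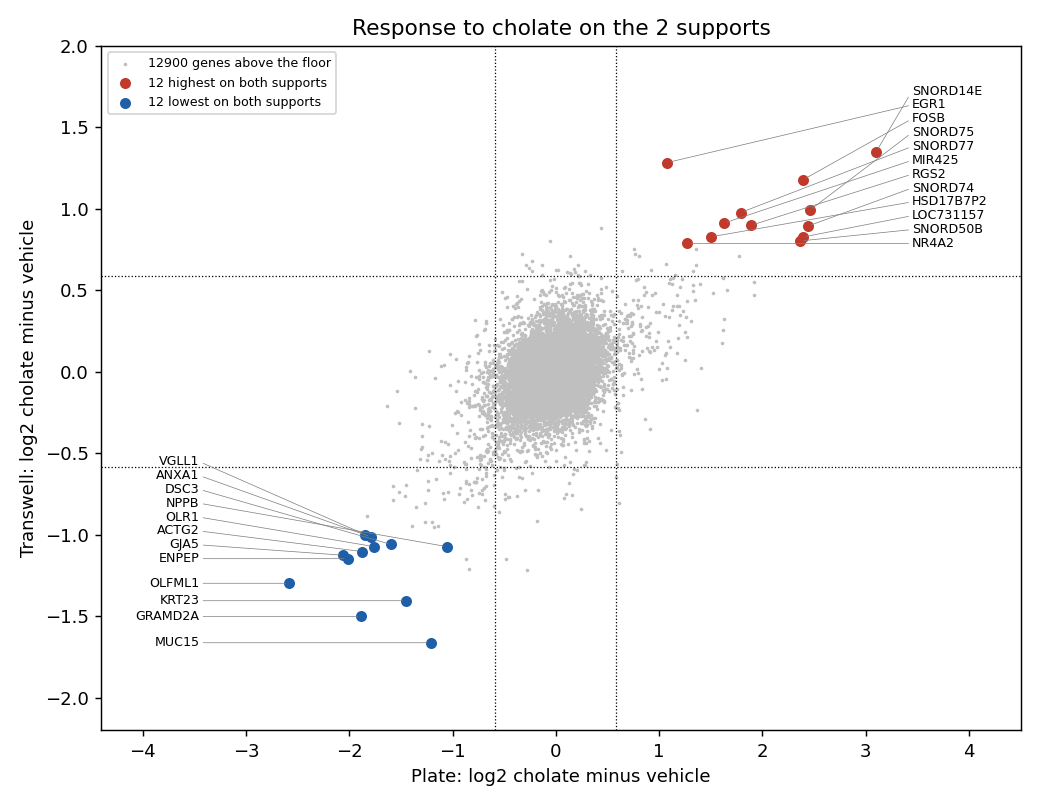
Log2 difference between cholate and vehicle on the plate (horizontal axis) and on Transwell (vertical axis) for 12900 genes above the floor, 1 pooled array per condition, with dotted lines at 1.5-fold and the 12 highest and 12 lowest genes named. The named genes lie beyond the lines on both axes, from OLFML1 at -2.58 on the plate to SNORD14E at 3.10.

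Of all probe sets above the floor, 170 were at least 1.5-fold higher on both supports, where independent lists would share 18.6, and 88 were lower on both, where 5.64 would be shared. The balance was the opposite among probe sets with a listed gene, a subset chosen after the data were seen: 29 were higher (1.02 if independent) and 74 lower (2.44). Some probe sets were at least 1.5-fold apart in opposite directions. Of all above the floor, 41 were higher on the plate and lower on Transwell, and 10 the reverse. With a listed gene these were 2 and 0. Opposite overlaps were not set against independent lists. Over all probe sets above the floor the responses correlated across genes at r of 0.366, against 0.457 with a listed gene, and genes are not independent replicates. No probe set passed the additive limma test for cholate. The smallest adjusted p was 0.312, and 2162 of 19978 had an unadjusted p under 0.05 where chance gives 999.

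The immediate early list showed the largest median. Of 40 measured members, 29 were higher and 3 lower on both supports, and the median was 0.33 log2 on the plate and 0.20 on Transwell, above all matched random lists (percentile 100). Over all probe sets 0 members passed limma, and 9 passed adjusted over the list alone, all higher: FOSB, JUNB, ATF3, EGR1, IER5, DUSP1, ZFP36, NR4A1 and NR4A2. ATF3 was higher by 1.09 and 0.55 log2 and JUNB by 0.77 and 0.73. In the list of EGF receptor ligands and feedback genes (19 measured, mean median -0.03, percentile 31.7), HBEGF, a ligand of that receptor, was higher by 0.76 on both supports and passed adjusted over the list alone.

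Genes of cholesterol synthesis and uptake were higher on both supports in 14 of 19 measured members and lower in 3, with a median of 0.16 log2 on the plate and 0.14 on Transwell (percentile 100 for both). INSIG1, a sterol-regulated retention protein of the SREBP pathway, was higher by 0.80 and 0.71, and the sterol oxidase gene MSMO1 by 0.48 and 0.52. These 2 passed adjusted over the list alone and 0 passed over all probe sets. SQLE was higher by 0.36 and 0.32. The list of fatty acid synthesis genes had a median of -0.06 (15 measured, percentile 21.5), with the desaturase gene FADS2 at -0.87 and -0.56.

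In the unfolded protein and integrated stress response list, 15 of 33 members were higher and 8 lower on both supports, and 0 passed in either adjustment. Its median of 0.05 log2 (percentile 100) was -0.01 when each array was centred on its median. CHAC1 was higher by 1.16 and 0.59, TRIB3 by 0.85 and 0.52, DDIT4 by 1.19 and 0.29, and DDIT3, the transcription factor CHOP, by 0.64 and 0.62. The NRF2 list, genes of the oxidative stress response, lay lower, with 15 of 19 members lower and 1 higher on both supports and a median of -0.13 (percentile 0.1). HMOX1, heme oxygenase, stood at -0.69 and -0.79 and was its single member to pass adjusted over the list alone, with 0 over all probe sets. Heat shock genes had a median of -0.01 (19 measured, percentile 79.8), with 7 members higher and 7 lower on both supports. HSPA1L was higher by 1.22 and 0.57, DNAJB1 by 0.90 and 0.28 and HSPA6 by 0.72 and 0.34. The Transwell vehicle value of HSPA6 (4.52) lay under the floor. HSPB8 stood at -0.71 and -0.73 and passed adjusted over the list alone.

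Actin cytoskeleton and SRF or YAP target genes were lower on both supports in 12 of 19 members and higher in 4, with a mean median of -0.18 log2 (percentile 0.0). TAGLN, a smooth muscle actin-binding protein, stood at -0.75 and -0.83 and passed adjusted over the list alone, ANKRD1 stood at -0.81 and -0.21, and CALD1 at -0.40 and -0.38. The cell cycle list had 31 of 37 members lower and 2 higher on both supports, with a median of -0.25 on the plate and -0.10 on Transwell (percentile 0.0 for both). Its largest member, the cyclin gene CCNE1, stood at -0.57 and -0.16. Extracellular matrix and integrin genes had 16 of 34 members lower and 3 higher and a median of -0.08 (percentile 0.7), with SPARC at -1.30 and -0.32. Stem cell and WNT targets had 12 of 16 members lower and 1 higher and a median of -0.12 (percentile 0.6), with LGR5, an intestinal stem cell marker, at -0.51 and -0.39. In the last 3 lists 0 members passed limma in either adjustment.

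Interferon response genes were lower on both supports in 11 of 19 members and higher in 3 (median -0.11, percentile 0.7). IFIT1 stood at -0.74 on each support and passed adjusted over the list alone, and IFI6 stood at -0.48 and -1.15. Inflammatory cytokine and NF-kappaB genes had a median of 0.03 (37 measured, percentile 82.8), with the inhibitor gene NFKBIA higher by 0.67 and 0.32 and the cytokine gene IL18 at -0.38 and -0.76.

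Enterocyte brush border and absorption genes were higher on both supports in 20 of 38 measured members and lower in 3, with a mean median of 0.09 log2 (percentile 100) and 0 passing limma. ANPEP, aminopeptidase N, was higher by 0.51 and 0.26, sucrase-isomaltase (SI) by 0.33 and 0.20, and FABP2, the intestinal fatty acid binding protein, by 0.22 and 0.66, its plate values lying under the floor. The ferric reductase gene CYBRD1 went the other way, at -0.73 and -0.52, and was the single member at 1.5-fold in the mean. Goblet and Paneth cell markers had a median of 0.09 (21 measured, percentile 98.4), and leukocyte markers, of which 5 of 12 lay above the floor, one of 0.13 (percentile 99.1). Neither held under every alternative: the goblet median was 0.02 (percentile 90.1) after quantile normalization and 0.03 (90.9) after cyclic loess, and the leukocyte members above the floor had 0.07 (85.3). LYZ, a member of both lists, stood at -0.56 and -0.45 and passed adjusted over the leukocyte list alone. Secreted proteins of hepatocytes and fetal gut had a median of 0.04 (18 measured, percentile 98.9), which was -0.02 under median centring, and a mean of -0.05. The ribosomal protein list had a median of 0.01 (24 measured, percentile 98.2), which was -0.05 under median centring and at percentile 94.9 after quantile normalization.

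Targets of FXR, the nuclear receptor for bile acids, and bile acid transporters did not stand apart as a list, with a mean median of 0.01 log2 over 21 measured genes (percentile 75.9). The list took no account of direction. Members raised and members lowered by the receptor would offset in this median, so it cannot exclude an FXR response. None of the members reached 1.5-fold in the mean of the 2 supports, and 0 passed limma in either adjustment. CYP7A1 stood at -0.29 and -0.08, with all its values under the floor. SLC51A, a subunit of the basolateral bile acid exporter, was higher by 0.59 on the plate and 0.07 on Transwell. FABP6, the ileal bile acid binding protein, was higher by 0.23 and 0.41. UGT2B4 stood at -0.69 and -0.07. The classical targets FGF19 (0.05 and 0.09) and NR0B2 (-0.04 and 0.37) were named after their values were seen; all values of FGF19 and the Transwell vehicle value of NR0B2 lay under the floor. Tight junction genes likewise had a median of -0.00 (28 measured, percentile 76.4), with 0 members at 1.5-fold on either support; CLDN5 was higher by 0.23 and 0.34 and TJP1 stood at -0.27 and -0.17.

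The other lists below stayed inside the central 95% of random lists for cholate. Their medians were -0.07 for adherens junctions and desmosomes (percentile 20.9), -0.05 for xenobiotic receptor targets (16.5), -0.03 for metallothioneins (39.4) and -0.04 for PPAR targets (30.8). Among the rest, p53 targets stood at 0.03 (91.2), apoptosis regulators at -0.01 (62.9), colonocyte markers at 0.02 (82.5), enteroendocrine and tuft cell markers at 0.02 (45.7) and fibroblast markers at -0.03 (8.1). Autophagy and lysosome genes stood at -0.06 (22.8), glucocorticoid, circadian and FOXO targets at 0.06 (97.1, but 98.5 after quantile normalization and 98.2 after cyclic loess), ion and water transport genes at -0.04 (18.2), housekeeping genes at -0.05 (35.7) and respiratory chain genes at -0.04 (44.2). Single members stood out in some of them. The kinase gene PLK2, a p53 target, was higher by 1.32 and 0.53. PMAIP1, which encodes the BH3-only protein NOXA, was higher by 0.93 and 0.63, and the incretin gene GIP stood at -0.92 and -0.71, both passing adjusted over their lists alone.

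**Figure D2:**
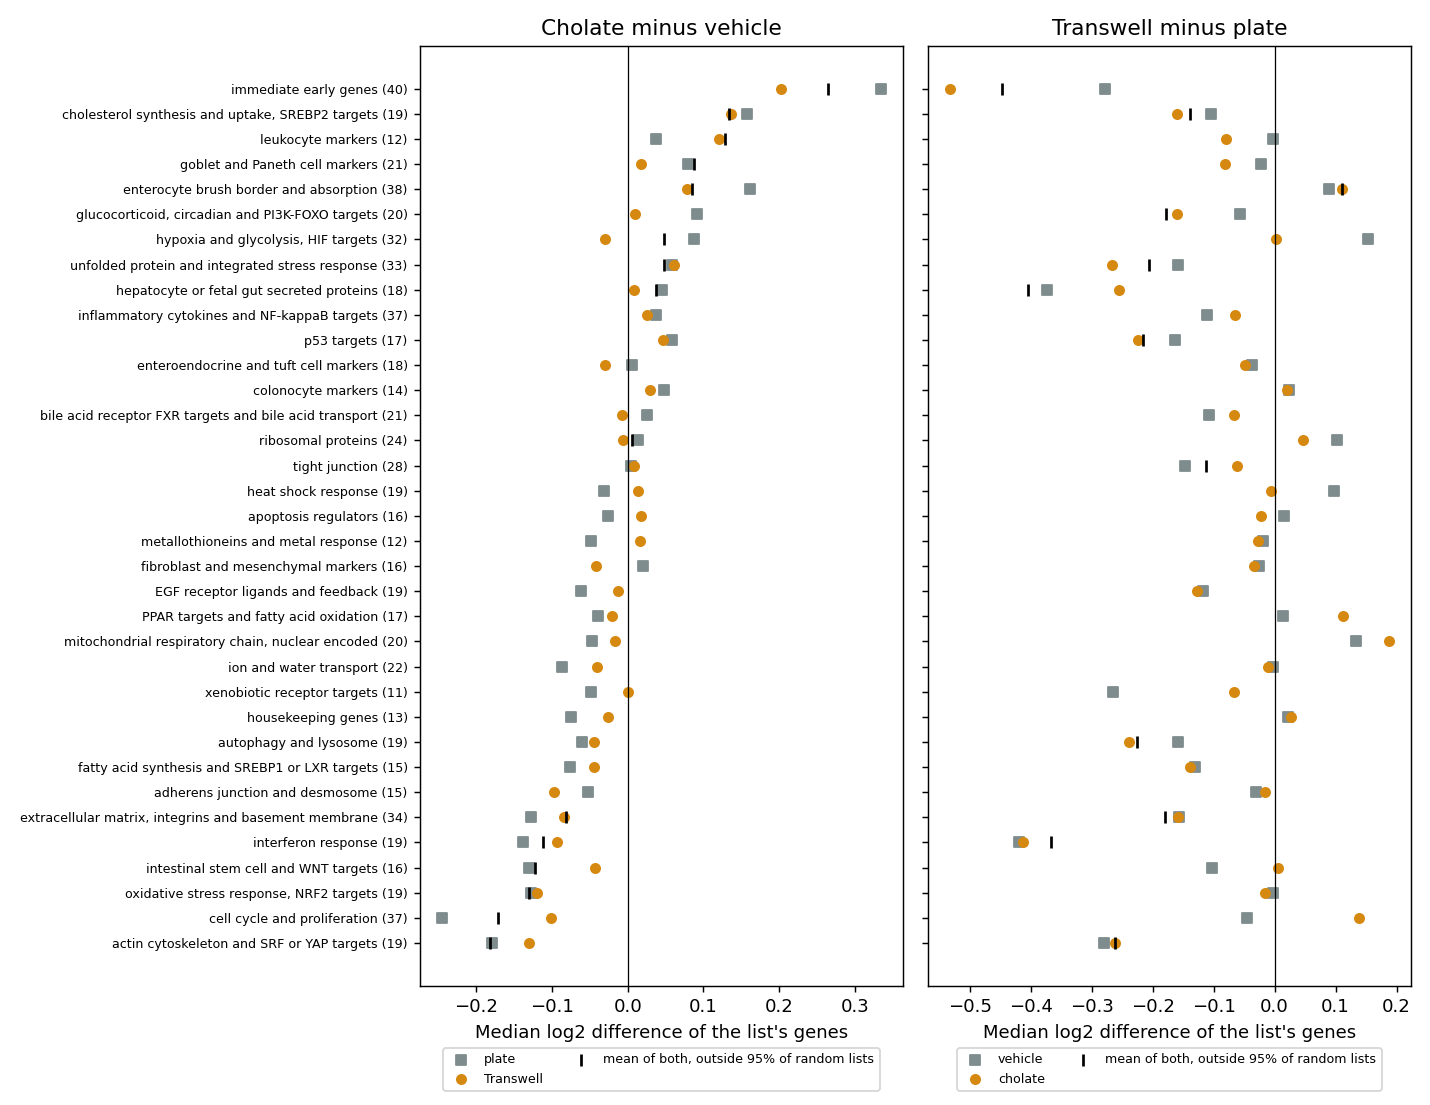
Median log2 difference of 35 gene lists (measured members in brackets) for cholate minus vehicle (left) and Transwell minus plate (right), with squares and circles for the 2 separate pairs of arrays and a black bar at the median of the gene means where it lay outside the central 95% of matched random lists. Immediate early genes lie highest for cholate, at 0.33 on the plate and 0.20 on Transwell, and have the lowest mean median, -0.45, for Transwell against plate; under median centring the cholate medians of the stress response, HIF, hepatocyte and ribosomal lists turn negative.

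On the plate alone, 1045 probe sets were at least 1.5-fold higher and 462 lower in cholate, and on Transwell 356 were higher and 244 lower. Probe sets without a listed gene made up most of the higher ones. What these measure is not given in the annotation used here, and controls or intronic probe sets among them were not told apart, so the totals are not counts of genes. With a listed gene the plate gave 260 higher and 337 lower and Transwell 58 and 107. Under median centring the splits were 880 against 644 on the plate and 279 against 311 on Transwell. Of the 260 higher on the plate, 88.5% were also above 0 on Transwell, and of the 337 lower, 84.9% were also below 0. The slope of the Transwell response on the plate response was 0.29 among listed genes. The 5 highest and 5 lowest genes on each support were among those already named, except ERVFRD-1, an endogenous retroviral envelope gene known as syncytin-2 in placenta, at -1.22 on Transwell and -0.28 on the plate.

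Responses differed between the supports by at least 1 log2 unit at 403 probe sets, 90 with the higher response on Transwell and 313 with the higher response on the plate; 19 and 45 of these had a listed gene. This difference has no test, since it uses all 4 arrays. The genes with the most positive difference were lower in cholate on the plate and near 0 on Transwell: the protease-like gene CAPN6 (-1.64 and -0.21), the iron carrier transferrin (TF, -1.42 and 0.01), KRTAP3-1 (-1.53 and -0.12), haptoglobin (HP, -1.23 and 0.13) and FAM230B (-1.36 and -0.03). In vehicle on Transwell, CAPN6 (4.80) and HP (4.66) already lay under the floor of 4.84 and KRTAP3-1 (5.21) close to it, so a lower value could hardly show there for these 3. TF read 7.3 in plate vehicle, 5.9 in plate cholate and 6.1 in both treatments on Transwell. Likewise KRTAP3-1 read 6.7 in plate vehicle and 5.1 to 5.2 on the other arrays, HP 6.0 and 4.7 to 4.8, and CAPN6 6.6 and 4.6 to 5.0. For these genes a high plate vehicle pool and a response on the plate cannot be told apart. FAM230B differed, reading 5.8 in plate vehicle and 5.3 in both treatments on Transwell. In cholate on the plate, HP (4.74) and FAM230B (4.47) lay under the floor. The most negative differences belonged to SNORD14E, SNORD74, SNORD50B and LOC731157, higher on both supports, and to CFAP144P1 (1.37 and -0.23), whose plate vehicle value (4.24) lay under the floor. Hypoxia-inducible factor targets had a median of 0.09 on the plate (32 measured, percentile 100) and -0.03 on Transwell (percentile 35.5). BHLHE40 was higher by 1.07 on the plate and 0.11 on Transwell, and ANKRD37 stood at 1.02 and -0.05. ANKRD37 read 6.7 in plate vehicle, 7.8 in plate cholate, and 7.8 and 7.7 in vehicle and cholate on Transwell. For Transwell minus plate the list median was 0.15 in vehicle (percentile 99.9) and 0.002 in cholate (21.6). A low plate vehicle pool and a response on the plate cannot be told apart. The cholate median of this list over both supports was 0.05 (percentile 100), and -0.01 under median centring.

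The last comparison set Transwell against plate, once in vehicle and once in cholate. MTTP, which loads lipid onto apolipoprotein B, was higher by 2.84 log2 in vehicle and 2.90 in cholate (7.17-fold and 7.48-fold), a mean of 2.87 with a limma SE of 0.09. The ferroxidase gene CP was higher by 2.32 and 2.63, SLC51A by 2.33 and 1.81, the fatty acyl reductase gene FAR2 by 1.98 and 2.23, and the efflux pump gene ABCG2 by 1.58 and 1.73. IL1B, a cytokine, was higher by 2.15 and 1.75, and the amino acid transporter gene SLC7A9 by 1.60 and 1.45. C17orf78 (2.27 and 2.16), CEACAM20 (1.98 and 1.82), ST8SIA6 (1.78 and 2.29), GDPD2 (1.62 and 2.26) and LINC01559 (1.58 and 2.36) completed the 12 highest. Both plate values of C17orf78 (4.46 and 4.35) and the plate cholate value of ST8SIA6 (4.59) lay under the floor of 4.84, so these differences are taken against background.

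Genes lower on Transwell included SLC10A1, the hepatocyte bile acid importer NTCP, at -2.14 in vehicle and -2.06 in cholate, a mean of -2.10 with a limma SE of 0.09. Plasma protein genes were among them, with ORM1 at -1.77 and -2.03, APOH at -1.64 and -1.92 and ITIH2 at -1.56 and -1.50. So were the interferon-induced genes IFIT1 (-1.67 in each) and IFITM1 (-1.49 and -1.57), and EGR1 (-1.75 and -1.54). HEPACAM2 stood at -2.23 and -2.53, with both Transwell values (4.42 and 4.09) under the floor and so near background, SNORA70F at -1.63 and -1.57, the arrestin-like gene ARRDC4 at -1.51 and -1.79, the elastic fibre gene FBLN5 at -1.50 and -1.47 and the trypsinogen gene PRSS1 at -1.73 and -1.43.

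**Figure D3:**
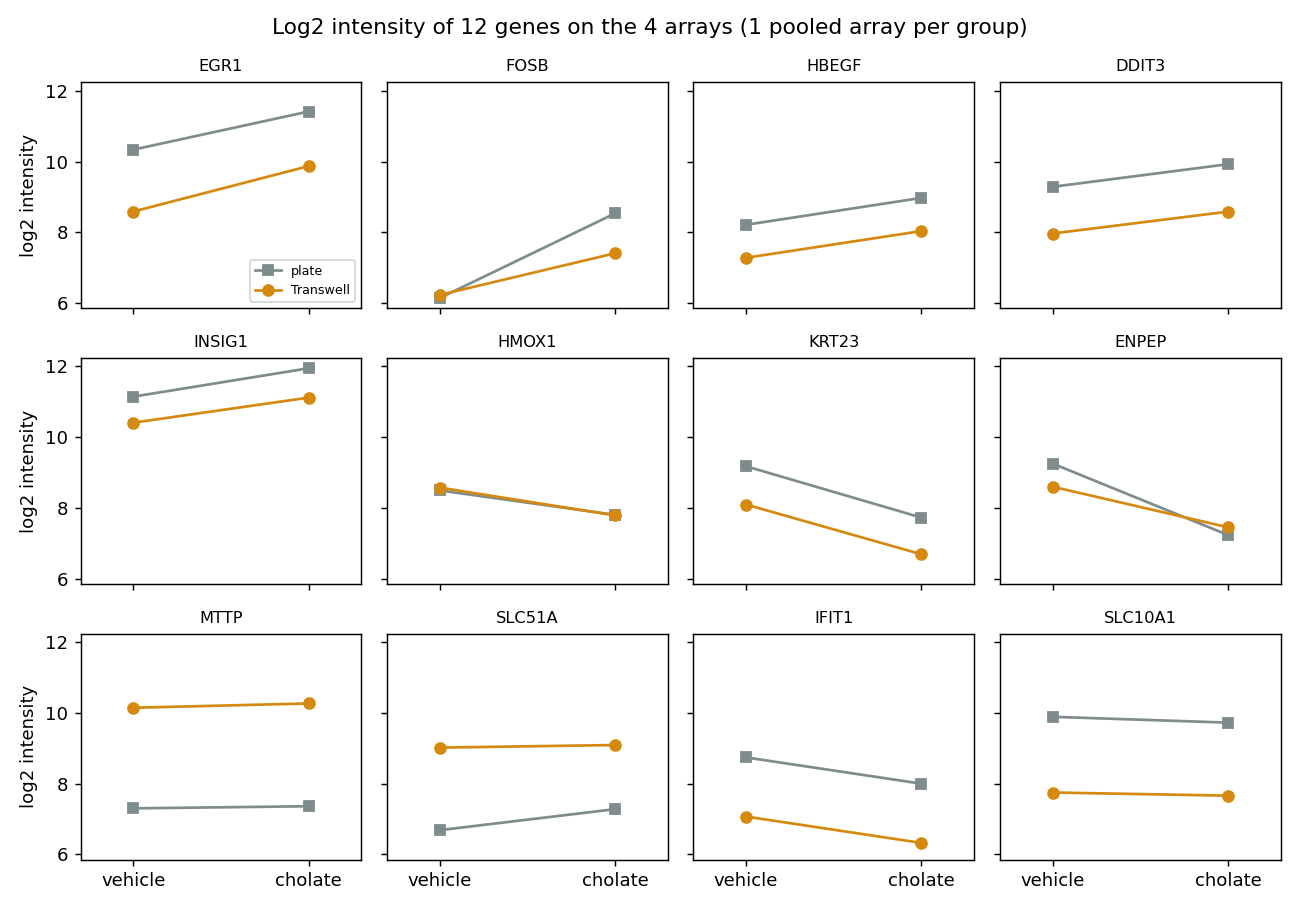
Log2 intensity (vertical axis) of 12 genes in vehicle and cholate on the plate (squares) and on Transwell (circles), 1 pooled array per point. EGR1 is higher in cholate on both supports and lower on Transwell, KRT23 and ENPEP are lower in cholate, and MTTP and SLC10A1 differ between supports by 2.84 and -2.14 in vehicle.

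In vehicle, 562 probe sets were at least 1.5-fold higher on Transwell and 662 lower, and in cholate 791 and 1126. With a listed gene these were 288 and 442 in vehicle and 585 and 546 in cholate. Under median centring the splits over all probe sets were 604 higher and 625 lower in vehicle and 976 and 974 in cholate. Among listed genes 174 were higher in both treatments (11.4 if independent) and 254 lower (16.3), and the differences correlated across genes at r of 0.688, against 0.512 over all probe sets. No probe set passed limma for support, where the smallest adjusted p was 0.0858 and 4519 had an unadjusted p under 0.05 (999 by chance). With a mean-variance trend 293 passed (105 higher, 188 lower), with a floor at the 60th percentile 807 passed, and among listed genes alone 1485 (731 higher, 754 lower).

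Enterocyte genes were the single list above the central 95% for support, with a mean median of 0.11 log2 (percentile 99.0). Of 38 measured, 20 were higher and 10 lower in both treatments. Of the 34 above the floor, 17 passed adjusted over the list alone, 12 of them higher. Over all probe sets 0 passed here and in every other list. Besides MTTP, FABP2 was higher by 1.03 and 1.46 over plate values under the floor (4.49 and 4.71), and the vitamin B12 receptor gene CUBN by 0.90 and 0.86, whereas the ferric reductase gene CYBRD1 stood at -1.01 and -0.80. Restricted to members above the floor, this list lay inside the range (percentile 97.4).

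Immediate early genes were lower on Transwell in both treatments in 29 of 40 members and higher in 4, with a mean median of -0.45 (percentile 0.0), and 18 passed adjusted over the list alone, all lower. CCN2 stood at -1.72 and -1.09 and JUNB at -1.13 and -1.17. Interferon genes were lower in 15 of 19 and higher in 0 (median -0.37, percentile 0.0), and 12 passed over the list alone, all lower, with IRF9 at -1.21 and -1.36. Hepatocyte-type secreted proteins were lower in 12 of 18 and higher in 3 (median -0.41, percentile 0.0, 7 passing over the list alone), with RBP4 at -1.11 and -1.33 and albumin (ALB) at -1.03 and -0.80. The actin and YAP list was lower in 17 of 19 and higher in 2 (median -0.26, percentile 0.0, 8 passing), and the unfolded protein list was lower in 24 of 33 and higher in 6 (median -0.21, percentile 0.0, 9 passing), with DDIT3 at -1.32 and -1.34.

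Lower medians outside the range were also seen for autophagy and lysosome genes (-0.23, percentile 0.0, 3 passing over the list alone, CTSL at -0.62 and -0.65) and p53 targets (-0.22, percentile 0.1, 6 passing, GDF15 at -0.73 and -1.16). The same held for glucocorticoid, circadian and FOXO targets (-0.18, percentile 0.1, 6 passing, the glucose phosphatase gene G6PC1 higher by 1.25 and 1.19), extracellular matrix genes (-0.18, percentile 0.0, 1 passing, TGFBI at -0.82 and -0.93), cholesterol genes (-0.14, percentile 0.2, 3 passing, INSIG1 at -0.74 and -0.83) and tight junction genes (-0.11, percentile 0.4). In the tight junction list 17 of 28 members were lower and 4 higher in both treatments, while its single member passing over the list alone, the pore-forming claudin gene CLDN2, was higher by 0.91 and 0.90. In the FXR and bile acid transport list (21 measured) the median was -0.07 (percentile 6.2). Of its 16 members above the floor 9 passed over the list alone, 4 of them higher. Its members above the floor had a median of -0.19 (percentile 0.1), outside the range, and cyclic loess gave -0.11 (1.8). Members above the floor also lay below the range in the lists of fatty acid synthesis (-0.16, percentile 0.7), inflammatory genes (-0.13, 0.4) and EGF receptor ligands and feedback (-0.18, 0.6), which with all members stood at -0.07, -0.07 and -0.06.

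Among the lists inside the range for support, members with the largest differences included the cytochrome gene CYP1A1 (1.36 and 1.51), the sterol exporter gene ABCA1 (-1.38 and -1.64), PMAIP1 (-1.12 and -1.42), the calcium-binding protein gene S100G (0.69 and 1.41), LGR5 (-1.38 and -1.27), PROM1 (-1.05 and -1.11) and the trefoil factor gene TFF1 (0.98 and 0.99). The medians of these lists ran from -0.07 for inflammatory genes (percentile 2.8) to 0.14 for respiratory chain genes (percentile 96.8).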

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

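Counting only listed genes was chosen after seeing the data; the other alternatives were planned. The 165 genes named for cholate and the 153 named for support kept their direction under quantile normalization, median centring and cyclic loess, with the largest shift 0.07 log2. Counts of probe sets stayed within 1.5 times the main ones under those 3 normalizations. They moved with the threshold and the floor, which change how many are eligible. The exception was support with no floor, where 1811 in vehicle and 2679 in cholate stayed within 1.5 times the main counts. At 2-fold, the counts were 110 for cholate on Transwell, 516 on the plate, 264 for support in vehicle and 451 in cholate. With no floor they were 1099 and 2304 for cholate on Transwell and plate, and with the 60th percentile floor 199 and 743, with 648 and 1151 for support in vehicle and cholate. With listed genes only they were 165, 597, 730 and 1131 in the order given for 2-fold. The difference of responses gave 1389 probe sets at 1.5-fold, 797 with no floor, 126 with the higher floor and 64 with listed genes.

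For cholate over both supports limma gave 0 under every variance model, floor and normalization tried, and 258 probe sets were at least 1.5-fold apart the same way in both pairs. For support it gave 293 with a variance trend, 807 with the higher floor and 1485 with listed genes, 0 under the others, and 558 by the rule of both pairs. The correlation of cholate responses was 0.254 with no floor, 0.503 with the higher floor and 0.457 with listed genes. Why these counts and correlations moved was not tested beyond the change in the probe sets used; the cause of the calls under the variance trend was not tested.

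Of the list medians for cholate, median centring turned the unfolded protein list to -0.011, HIF targets to -0.01, secreted proteins of hepatocytes to -0.022 and ribosomal proteins to -0.052. The mean of the hepatocyte list was -0.052, from -0.121 on the plate and 0.018 on Transwell. A mean is moved by single members, and over both supports TF stood at -0.704 and HP at -0.551. Centring shifts every mean cholate difference by the same 0.06 log2, which by construction turns small positive medians negative and leaves percentiles as they were. Restricting lists to members above the floor gave 15 lists outside the range for support, 0 higher and 15 lower, against 12 with all members, 1 higher and 11 lower. For cholate it gave 14 against 15, as did quantile normalization. Single samples could not be paired because the labels give no replicate numbers and each condition has 1 array. The additive model did compare cholate with vehicle within each support. Leaving out an array was not run, since it leaves no residual degree of freedom. Signal close to background limits small RNAs and markers of other cell types, many of which lay below the floor.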

Other observations

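The groups of small nucleolar, small nuclear, microRNA, histone, long nuclear, short cytoplasmic and trophoblast genes were formed after the highest and lowest genes were seen, and 4 choices followed the first test values: trophoblast markers above the floor, a narrower short cytoplasmic group, the weighing of small nuclear RNAs and that of the size of the cyclic loess shifts. Small nuclear RNAs, the RNA parts of the spliceosome, had a median log2 difference for cholate of 0.46 on the plate and 0.16 on Transwell over 20 probe sets, with 13 higher and 1 lower on both supports. At 1.5-fold, 9 were higher and 0 lower on the plate, and 2 were higher and 2 lower on Transwell. The minor spliceosome RNA RNU6ATAC was higher by 1.36 and 0.75. Clustered histone genes, whose mRNAs end in a stem-loop instead of a poly(A) tail, had medians of 0.13 and 0.09 over 57 probe sets. Of these 29 were higher and 10 lower on both supports, 8 were at least 1.5-fold higher in the mean, and 0 passed limma in either adjustment. MicroRNA precursors stood at 0.06 and 0.04 over 173. Among listed probe sets, MTLN (0.61 on the plate and -0.81 on Transwell) and ERVW-1 (0.59 and -0.65) were the 2 at least 1.5-fold apart in opposite directions, the Transwell cholate value of MTLN (4.66) lying under the floor.

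Small nucleolar RNAs were higher in cholate on the plate, with a median of 0.31 log2 over 175 probe sets, 53 of them at least 1.5-fold higher and 0 lower. On Transwell the median was 0.11, with 8 higher and 1 lower. The 5198 probe sets above the floor without a listed gene also leaned higher on the plate. Their median was 0.091, against -0.021 with a listed gene, and 785 were at least 1.5-fold higher and 125 lower. The lean was therefore not confined to the listed small nucleolar RNAs. Bootstrap intervals here and below come from 10000 resamples of the probe sets of a group on these same arrays. They measure the spread between probe sets, which can be regulated together, and not the spread between cultures. Normalization between the arrays stays open. The median was 0.286 (95% bootstrap interval 0.217 to 0.37) under cyclic loess. On values already normalized, however, cyclic loess moved no probe set above the floor by more than 0.061, and unprocessed intensities were not analysed here. A larger share of nuclear RNA in the plate cholate pool cannot be told apart from a cellular change: 7 long nuclear RNAs had a median of 0.058 with an upper bound of 0.15, narrowly below the 0.156 set beforehand, but that bound left out the small nuclear RNAs, nuclear too, at 0.459 (0.197 to 0.864). Better recovery or labelling of short RNAs is open as well, since the 5 short cytoplasmic RNAs measured had a median of 0.213 (-1.28 to 0.948) and only 2 lay above the floor; the group first held large ribosomal RNAs too, with a median of 0.035 over 9 probe sets. A cellular response to cholate may therefore account for the pattern, as may a difference in how the pool was prepared.

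Genes best known from placenta were among those lowest in cholate, such as VGLL1 and MUC15 among the 12 lowest on both supports. ERVFRD-1 was among the lowest on Transwell alone, at -1.22 against -0.28 on the plate. The 12 lowest genes had a median of -1.81 on the plate and -1.11 on Transwell. Normalization stays open here too, since cyclic loess, which gave a median mean response of -1.43 (-1.60 to -1.41) for these 12, moved no mean response above the floor by more than 0.058. RNA of placental or choriocarcinoma cells in the vehicle pools was tested on a marker list written before its values were looked at: all 33 markers not named by the rule had a median of -0.149 (-0.226 to -0.03), an interval wholly above -0.29, which had been set beforehand as arguing against this source. That bound was set wrongly, since 12 of the markers lay below the floor, where the median was -0.03 and no fall could be seen, so the 21 markers above the floor were tested after that result was seen; they gave -0.186 (-0.397 to -0.053), which spans the bound. Such RNA and a response of the Caco-2 cells themselves therefore cannot be told apart. Of the 33 markers, 17 were lower and 5 higher on both supports (13 and 2 of the 21 above the floor). Of all 34 measured, 22 lay above the floor and were tested with limma. Of these 22, 7 passed adjusted over the list alone, all lower. Single markers included XAGE3 at -1.25 and -0.54 and LGALS14 at 0.24 and 0.24.

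The trophoblast markers TFAP2C (10.2 on the plate vehicle array, 9.33 on the Transwell cholate array), PEG10 (11.8 and 10.9), HSD3B1 (9.12 and 8.76) and GATA3 (8.89 and 7.90) lay well above the floor in all 4 arrays, whereas CGA (5.20) and PSG1 (3.87) were at or near background on the plate vehicle array. By their mean over the 4 arrays, all 18 measured hepatocyte-type secreted protein genes and 34 of 38 enterocyte genes also lay above the floor. On the plate vehicle array TTR read 11.6, ALB 10.3 and SI 7.8. Authentication of the line is not given in the sources used here, so the identity and purity of the cells remain open.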
